A study of Mus musculus with 3 samples.

How the data were processed

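C2C12 myotubes that had differentiated for 72 h were exposed for 3 h to CDDO-Im at 100 nmol/L, fixed with formaldehyde and immunoprecipitated with an antibody against Nrf2, per the labels' protocols. The labels give 2 ChIP replicates and 1 input. A peak list of each ChIP replicate was analysed, and the reads of the input are not used here. Nothing in the labels says whether the replicates came from separate cultures, so the p-values measure only the agreement of these 2 samples, whose differences may be technical.

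Per the submitters' processing notes, the tools were bcl2fastq 2.15.0, Bowtie2 (version not given in the sources used here) and MACS 1.4, with the mm9 build. The notes give these names without roles, order or settings. Each ChIP sample has its own list, so the replicates can be compared by the overlap of separately listed peaks. Whether the input served as the control for either or both lists is not given in the sources used here. Peaks that arise from a control used for both lists would appear in both, and overlap does not exclude them. A list gives the start, end and score of each peak. The score is the authors' deposited value. It was read as minus 10 times log10 of the caller's p-value, because MACS 1.4 writes this quantity and the lowest scores are 50, which would be a caller threshold of 1e-05. The score was used to describe, rank and filter peaks within a list. It depends on depth, so no difference in binding between replicates was read from it. The depth of each sample is unknown, and intervals on shares cover counting error only.

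Peaks of different replicates were called shared when they overlapped by at least 1 bp, and chains of overlapping peaks were merged into shared regions. The share expected from placement alone was taken from 1000 circular shifts of 1 list within each chromosome, with each chromosome's length set to the largest peak end in either list (one-sided permutation test). The agreement of scores was Spearman's rho over the shared regions, each with its best score in each replicate (two-sided permutation test, 100000 permutations). Shares have 95% Wilson intervals. A peak was called dense when at least 2 other peaks of its list lay within 100 kb (between centres, as for all distances given), and isolated otherwise. For shared regions, neighbours were counted among the shared regions. Ratios of peak densities have 95% intervals from 1000 bootstrap draws of 10 Mb windows. The overlap test was checked on the 2892 peaks of replicate 1 against simulated lists, made from the shifted peaks of replicate 2. Into these lists 0, 500 or 1500 exact copies of replicate 1 peaks were planted. Exact copies must overlap, so finding 100% of them checks the code only and not the sensitivity to partial overlap. With 500 or 1500 copies the permutation p was 0.0099, the smallest that 100 shifts can give. With 0 copies, 7 peaks were called shared (permutation p = 0.832).

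The tests of overlap and rank agreement, the rule for the named regions and their first alternatives were fixed before the data were examined. The named regions are the 20 shared regions that rank best by the worse of their ranks in the 2 replicates, with ties ordered by the better rank. These alternatives were overlap of at least 50% of both peaks, peak centres within 200 bp, peaks with a score of at least 100, and the 1000 highest-scoring peaks of each list. Local shifts of 5 to 50 kb, chromosomes 2 to 19 alone, and isolated peaks alone were added after seeing the data. The comparisons by chromosome and along chromosome 1 were also chosen after seeing the data.

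Position classes of the regions relative to genes, counts over 14 gene lists and motif shares had been planned. They needed an annotation and a sequence of the mm9 build. The gene table at hand is of the GRCm38.p6 assembly, no coordinates were converted between builds, and these analyses were not run. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.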

Results

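Binding of the transcription factor Nrf2 to chromatin was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in C2C12 myotubes. C2C12 is a mouse myoblast line whose cells fuse into muscle fibre-like myotubes when serum is reduced. The cells had differentiated for 72 h and were then exposed for 3 h to CDDO-Im at 100 nmol/L. CDDO-Im is a synthetic triterpenoid that activates Nrf2, a factor known for switching on antioxidant and detoxification genes. The labels name 2 ChIP replicates and 1 input, and a peak list of each ChIP replicate was analysed here. All samples received the compound, so the lists show where Nrf2 ChIP signal lay in treated myotubes and not what the treatment changed. Read totals are not given in the sources used here, so the sequencing depth behind each list is unknown. All positions are in the mm9 build and count from 1.

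The lists held 2892 peaks in replicate 1 and 3593 in replicate 2. The peaks of replicate 1 covered 1.66 Mb and had a median width of 456 bp. Those of replicate 2 covered 2.68 Mb and had a median width of 612 bp. Each peak carried the authors' own score, which was read as highest for the peaks that the caller rated least likely to arise from background. In both lists most peaks lay near the lower end of the scores, with a median of 80.0 in replicate 1 and 88.7 in replicate 2. A score of at least 100 was reached by 976 peaks (33.8%) of replicate 1 and by 1562 peaks (43.5%) of replicate 2. A score of at least 200 was reached by 285 and 660 peaks. The highest score was 1933 in replicate 1, on chromosome X, and 3100 in replicate 2, on chromosome 13.

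The first comparison asked whether the duplicates placed Nrf2 at the same positions. Of the 2892 peaks of replicate 1, 1913 overlapped a peak of replicate 2 by at least 1 bp, which was 66.2% (95% Wilson interval 64.4 to 67.9%). Of the 3593 peaks of replicate 2, 1797 overlapped a peak of replicate 1, which was 50.01% (48.4 to 51.7%). When the peaks of 1 list were shifted around each chromosome, a mean of 0.433% of the peaks of replicate 1 and 0.32% of those of replicate 2 overlapped. The one-sided permutation p was 0.001 for each replicate, the smallest that 1000 shifts can give. The overlapping peaks merged into 1750 shared regions with a median width of 710 bp, of which 1613 held 1 peak of each replicate. In 1485 shared regions (84.9%) the peak or peaks of replicate 2 had a longer span, any gaps between peaks included, than those of replicate 1.

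Peaks missing from the other list were mostly low in score. In replicate 1 the overlap rose from 46.0% of the 1295 peaks with a score from 50 to 75 to 100% of the 36 peaks with a score of at least 500. In replicate 2 it rose from 30.1% of 1398 peaks to 100% of 171 peaks over the same classes. Among peaks with a score of at least 200, 283 of 285 in replicate 1 (99.3%, Wilson interval 97.5 to 99.8%) and 602 of 660 in replicate 2 (91.2%, 88.8 to 93.1%) had a partner. The highest-scoring peak without a partner in replicate 1 was a dense one at chromosome 8, 19872690 to 19874833, with a score of 336. In replicate 2 it was an isolated one at chromosome 10, 66488462 to 66489271, with a score of 348. The Wilson intervals cover counting error only. The number of shared regions fell to 659 when only peaks with a score of at least 100 were used and to 903 when only chromosomes 2 to 19 were used.

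**Figure D1:**
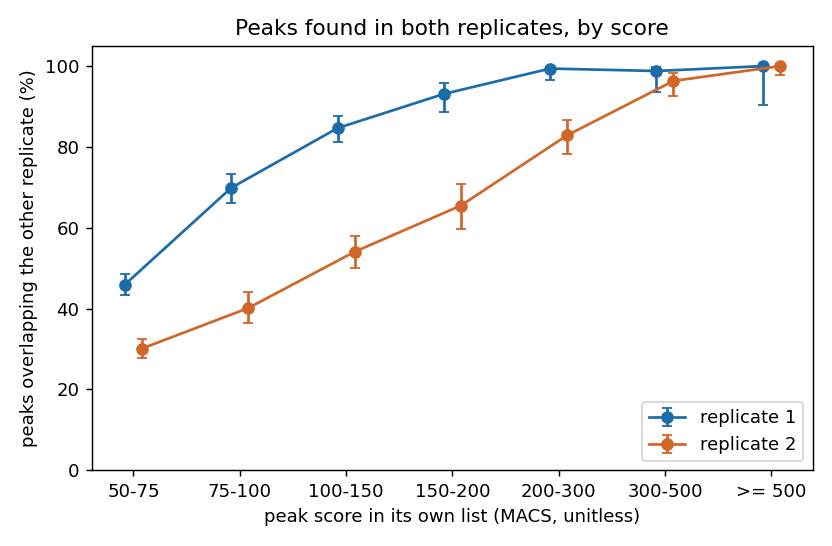
Percentage of peaks that overlapped a peak of the other replicate by at least 1 bp (vertical axis), by the peak's score in its own list (horizontal axis, no unit). Points are the 2 replicates and bars are 95% Wilson intervals. The overlap rose from 46.0% and 30.1% in the lowest class to 100% in both replicates at a score of at least 500.

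The second comparison asked whether regions with strong peaks in 1 replicate also had strong peaks in the other. Over the 1750 shared regions, Spearman's rho between the best scores of the replicates was 0.513 (two-sided permutation p = 1e-05, the smallest that 100000 permutations can give). This correlation is across regions, which are not independent replicates. In 229 shared regions both replicates had a score of at least 200, and in 31 both had at least 500. Of the 229, 129 had fewer than 2 other shared regions within 100 kb. These 129 regions included 107 on chromosomes 2 to 19, with at least 1 on each of the 18, 18 on chromosome 1 and 3 on chromosome X.

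The 20 shared regions that ranked highest in both replicates lay on 12 chromosomes or unplaced sequences. The first was a region of 970 bp on chromosome 13 (12905848 to 12906817), with a score of 1855 in replicate 1 and 3100 in replicate 2, and 3 other shared regions lay within 100 kb of it. The second, of 914 bp, lay on chromosome 4 (14825608 to 14826521), with scores of 1075 and 2309. A pair of regions on chromosome 8, ranked 3 and 6, had centres 5756 bp apart. The region of rank 3 spanned 77613208 to 77614066 and scored 1073 and 2051, and that of rank 6 spanned 77607411 to 77608351 and scored 869 and 1749. Rank 4 was a region on chromosome X (73843806 to 73844674), where replicate 1 had its highest score of 1933 and replicate 2 scored 1649. Rank 5 was a region on chromosome 11 (75196743 to 75197642), with scores of 999.8 and 2373. Ranks 8 and 9 were regions on chromosome 3 (95848213 to 95849199) and chromosome 16 (14350515 to 14351454). They scored 1801 and 793 in replicate 1 and 1436 and 1896 in replicate 2.

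Further down the same order, chromosome 13 held a region at 13117818 to 13118636 (scores 761 and 1576) and one at 13260512 to 13261577 (628 and 1624). Chromosome 19 held one at 4045613 to 4046658 (747 and 1763), and chromosome 5 one at 144175395 to 144176414 (592 and 1574). Regions on chromosome 2 (112273289 to 112274175) and on chromosome 4 (132179887 to 132180730) scored 559.9 and 606 in replicate 1 and 1335 and 1179 in replicate 2. The last of the 20 lay on chromosome 1 (45916890 to 45917827), with scores of 546 and 1546, and had 4 other shared regions within 100 kb. All of these regions, 15 of the 20, were narrower than 1100 bp.

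The remaining 5 of the 20 were wide and lay among other peaks. They were on chromosome 4 (146017355 to 146026451, and 145036318 to 145040593), chromosome 16 (3241135 to 3245173), chromosome 5 (15017974 to 15024055) and an unplaced sequence of chromosome 8 (692781 to 695247). Their widths ran from 2467 to 9097 bp, and their scores were 866 to 1231 in replicate 1 and 1197 to 1504 in replicate 2. In all, 7 of the 20 regions had at least 2 other shared regions within 100 kb. No gene annotation of the mm9 build was used here, so the regions are named by position and their genes are not reported.

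**Figure D2:**
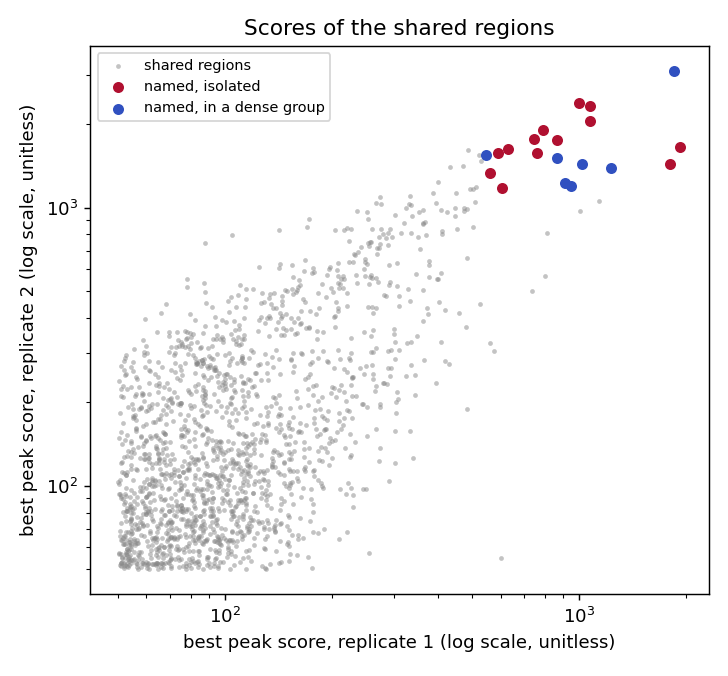
Best peak score in replicate 1 (horizontal axis) and in replicate 2 (vertical axis) for each of the 1750 shared regions, both on log scales without unit. Large points are the 20 named regions, in red where fewer than 2 other shared regions lay within 100 kb and in blue otherwise (7 regions). The named regions scored at least 546 in replicate 1 and 1179 in replicate 2.

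Peaks were spread unevenly over the chromosomes. Among the numbered chromosomes and X they were densest on chromosomes 1 and X, followed by chromosome 4 with 246 peaks in replicate 1 and 293 in replicate 2. Chromosome 1, which made up 7.55% of the span of the numbered chromosomes and X, held 909 peaks (31.4%) of replicate 1 and 729 (20.3%) of replicate 2. Chromosome X, with 6.37% of the span, held 566 (19.6%) and 515 (14.3%). Chromosomes 2 to 19 together held 1312 peaks of replicate 1 and 2238 of replicate 2. Among peaks with a score of at least 200, chromosome 1 held 57 of 285 in replicate 1 (20%, Wilson interval 15.8 to 25.0%) and 68 of 660 in replicate 2 (10.3%, 8.21 to 12.9%), and chromosome X held 54 (18.95%) and 78 (11.8%). Among those with a score of at least 500, chromosome 1 held 2 of 36 in replicate 1 (5.56%, Wilson interval 1.54 to 18.1%) and 12 of 171 in replicate 2 (7.02%, 4.06 to 11.9%). Chromosome X held 1 of the 36 and 12 of the 171.

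Peaks with a score below 100 were 8.17 times as dense on chromosome 1 as on chromosomes 2 to 19 in replicate 1 (95% bootstrap interval 5.25 to 12.0) and 4.60 times as dense in replicate 2 (3.16 to 6.42). Peaks with a score of at least 200 were 3.94 times as dense in replicate 1 (1.97 to 7.04) and 1.54 times in replicate 2 (1.08 to 2.16). The excess at low scores was 2.07 times that at high scores in replicate 1 (1.33 to 3.49) and 2.99 times in replicate 2 (2.23 to 4.17). Among isolated peaks with a score of at least 200 the ratio was 1.39 (0.64 to 2.26) and 1.20 (0.837 to 1.56), but the crowding of chromosome 1 itself removes peaks from this class, which kept 13 of its 57 such peaks in replicate 1 and 41 of 68 in replicate 2. On chromosomes 2 to 19 alone, 71.7% of the peaks of replicate 1 and 40.8% of those of replicate 2 had a partner, each with a permutation p of 0.001.

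**Figure D3:**
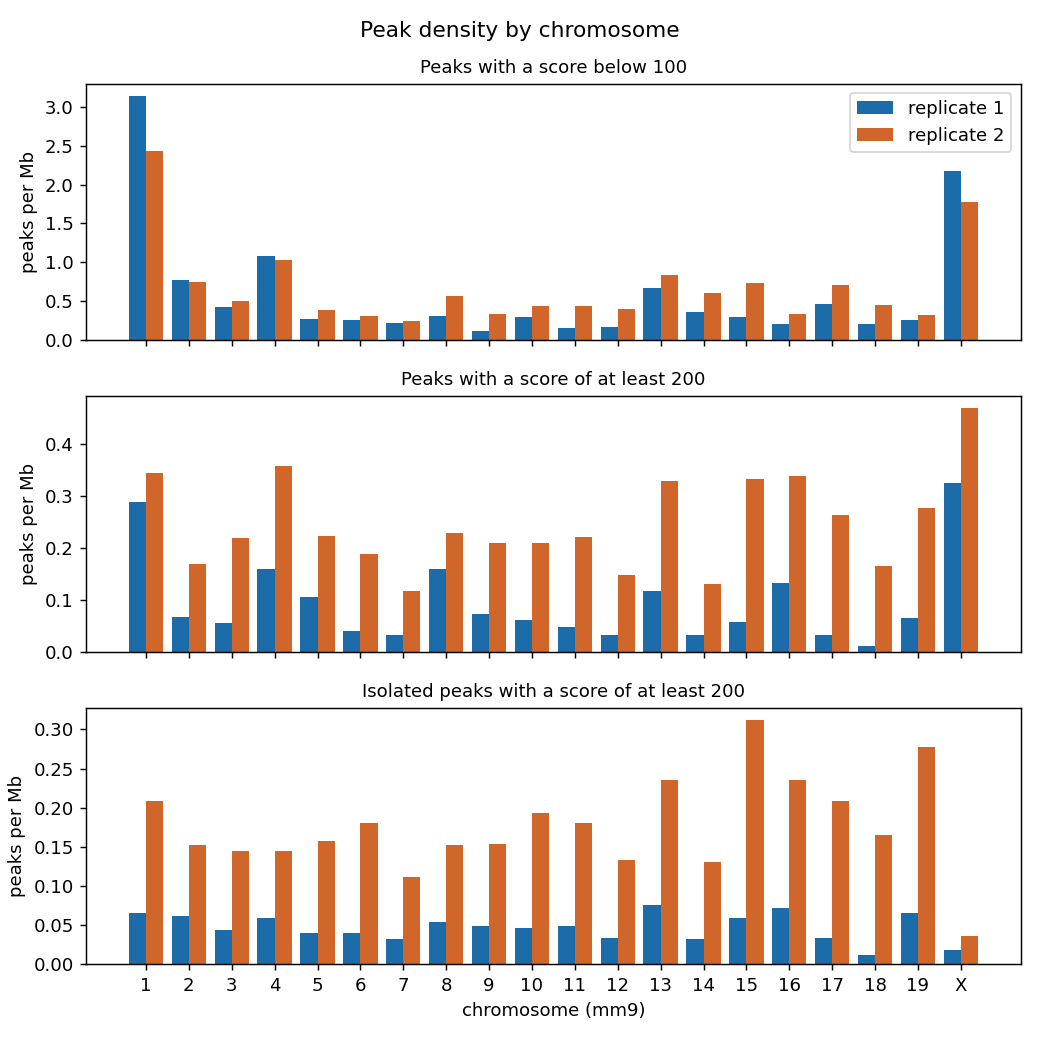
Peaks per Mb (vertical axes) on each chromosome of the mm9 build (horizontal axis) in both replicates, for peaks with a score below 100, peaks with a score of at least 200, and those of the latter that were isolated. Chromosome 1 held 618 and 479 of the low-scoring peaks and 57 and 68 of the high-scoring ones, of which 13 and 41 were isolated.

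On chromosome X, 498 of the 566 peaks of replicate 1 and 408 of the 515 of replicate 2 lay in the stretches from 3 to 5 Mb and from 23 to 33 Mb. On chromosome 1 the peaks were densest at its start. The first 5 windows of 10 Mb held 333 peaks with a score below 100 in replicate 1 and 246 in replicate 2, and the last 5 of the 19 full windows held 68 and 55.

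**Figure D4:**
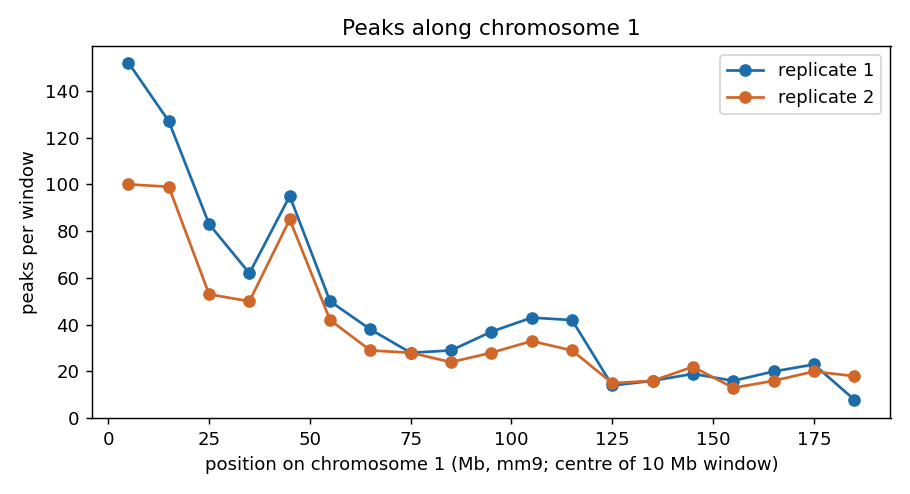
Peaks per 10 Mb window (vertical axis) along chromosome 1 of the mm9 build (horizontal axis, Mb) in both replicates. Both lines fall from 152 and 100 peaks in the first window to 8 and 18 in the last of the 19 full windows.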

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

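The settings with chromosomes 2 to 19 alone, isolated peaks alone and local shifts were chosen after the data were seen. The overlap of the lists and the rank agreement of scores passed their permutation tests under every alternative that was run for them. The overlap ranged from 52.2 to 72.3% of the peaks of replicate 1 and from 36.5 to 54.6% of those of replicate 2, and rho ranged from 0.543 to 0.616. Local shifts gave a mean overlap of 7.0 and 4.98%, more than shifts along whole chromosomes and below the observed values. Of 30 alternative values, 20 kept their call or stayed within 1.5 times the main count, and 10, all counts, moved further. The number of shared regions was 659 with scores of at least 100, 538 with the 1000 highest-scoring peaks, 903 on chromosomes 2 to 19 and 785 among isolated peaks. The number of peaks in replicates 1 and 2 was 976 and 1562 with scores of at least 100, 1312 and 2238 on chromosomes 2 to 19, and 1255 and 2152 among isolated peaks. These counts fell because fewer peaks entered. Leaving out a replicate leaves no pair of lists to overlap, so it gave no value. No paired analysis was possible because there is 1 ChIP group. Alternatives for position classes, gene lists and motifs were not run, for want of an mm9 annotation and sequence. The unknown depth of the samples limits any reading of the peaks found in 1 list only.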

Other observations

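The tests in this part were all chosen after the pattern they concern had been seen, and the bound used for the decline along chromosome 1 was made stricter after its value was known. Under the earlier bounds, a rho below -0.5 and then also below that of every other chromosome, an even gain had counted as excluded. Dense groups of peaks recurred at the same places in both lists. Of the peaks of replicate 1, 1637 (56.6%) were dense, and of those of replicate 2, 1441 (40.1%). The stretch of chromosome X from 23 to 33 Mb held 311 peaks in replicate 1 and 250 in replicate 2, and that from 3 to 5 Mb held 187 and 158. Chromosome 4 had 151 and 147 peaks in a stretch of 3 Mb that held its named regions at 145036318 and 146017355, and chromosome 13 had 60 and 51 from 65 to 67 Mb. Chromosome 17 had 27 and 38 from 38 to 39 Mb, and chromosome 8 had 32 and 22 from 19 to 20 Mb. Peaks with a score of at least 500 lay in the stretch on chromosome 4 (4 in replicate 1 and 8 in replicate 2) and in that on chromosome 8 (5 and 4). On chromosome X they lay there in replicate 2 only, 5 from 23 to 33 Mb and 2 from 3 to 5 Mb. The stretches on chromosomes 13 and 17 held 0 such peaks in both replicates. What sequence these stretches hold was not examined here.

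Low-scoring peaks were crowded on chromosome 1 in both replicates. Peaks with a score of at least 200 were crowded there too over all peaks, but not detectably among isolated ones (ratios 1.39 and 1.20, intervals including 1). At a score of at least 500 chromosome 1 held 5.56% of 36 peaks in replicate 1 (95% Wilson interval 1.54 to 18.1%). In replicate 2 it held 7.02% of 171 peaks (4.06 to 11.9%). Both intervals include its 7.55% of the span and larger shares too, so an excess at these scores is not excluded. An equal concentration of sites of every strength was argued against, because over all peaks the excess below a score of 100 was 2.07 times that at 200 or more in replicate 1 (95% bootstrap interval 1.33 to 3.49) and 2.99 times in replicate 2 (2.23 to 4.17). This ratio was first taken among isolated peaks, a class from which crowding removes high-scoring peaks, and was 4.24 and 3.04 there. An unequal concentration of sites stays open. An even gain of the whole chromosome stays open. The density of low-scoring peaks declined with position (rho -0.848 and -0.891, permutation p = 1e-05 each, the smallest possible). On the other 19 chromosomes the lowest rho was -0.679 in replicate 1 and -0.743 in replicate 2. These came from chromosome 19 (6 windows, 13 peaks) and chromosome 16 (9 windows, 29 peaks). Chromosome 1 had 19 windows with 613 and 473 such peaks. Only in replicate 1 was rho on chromosome 1 more than 2 SD below the mean of those chromosomes (bounds -0.712 and -0.936). The bound of replicate 2 lay close to the lowest value that rho can take, so missing it says little. The SD of replicate 2, 0.405 against 0.25 in replicate 1, included a rho of 0.805 on chromosome 11. There the density rose with position, and such a value widens the bound. The chromosomes behind the SD had from 6 to 17 windows, so their rho values were not equally precise. Among isolated low-scoring peaks of chromosome 1 rho was -0.302 and -0.608, where leaving out dense peaks flattens any decline by construction. A processing step that followed chromosome order could not be decided, since the density of isolated low-scoring peaks over chromosomes 2 to 19 had a rho of -0.273 and 0.0918 with chromosome number (permutation p 0.272 and 0.716). For isolated peaks with a score of at least 200 this rho was -0.0341 in replicate 1 and 0.56 in replicate 2 (permutation p 0.895 and 0.0169). These tests left out chromosome 1. Isolated low-scoring peaks numbered 1.45 per Mb on chromosome 1 in both replicates, and 0.717 and 0.678 on chromosome 2. Over chromosomes 2 to 19 the values were 0.247 and 0.399, and chromosome 15 had 0.722 in replicate 2. Low-scoring peaks also declined with position along chromosome 2 (rho -0.637 and -0.532). A gain of part of chromosome 1 and thin coverage of it in a control were not tested, and the design names no biological difference to set against them.

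The replicates differed in where their peaks lay. The ratio of the number of peaks in replicate 1 to that in replicate 2 was 0.586 on chromosomes 2 to 19 (95% bootstrap interval 0.518 to 0.663) and 1.25 on chromosome 1 (1.13 to 1.35). On chromosome 1 it was 1.16 (0.962 to 1.32) at a score of at least 100 and 0.925 (0.83 to 1.04) among isolated peaks, a class that crowding itself reduces, and both of these intervals include equal numbers. The length covered by peaks gave ratios of 0.938 on chromosome 1 and 0.49 on chromosomes 2 to 19. Chromosome 1 was not the only place with more peaks in replicate 1, since chromosome X had 566 against 515. At a score of at least 100 the order on chromosome X reversed, with 204 peaks in replicate 1 and 218 in replicate 2. The peaks of chromosome X covered 379.1 kb in replicate 1 and 513.9 kb in replicate 2. By number of peaks, the dense stretches on chromosomes 4, 8 and 13 given above also had more in replicate 1, while that on chromosome 17 had fewer. These differences between stretches were not tested. Among all shared regions, 126 held 2 or more peaks of replicate 1 and 40 held 2 or more of replicate 2. A higher number of peaks therefore need not mean more signal. The ratio of the ratios on chromosome 1 and on chromosomes 2 to 19 was 2.13 (1.82 to 2.46), which restates the difference and was not used to weigh an explanation of it.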
